A study of Mus musculus with 21 samples.

How the data were processed

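RNA from small intestine of E18.5 mouse embryos was labelled and hybridised to Illumina WG6_V2 bead arrays, per the labels' protocols. There were 11 libraries labelled Prdm1+/+ and 10 labelled Prdm1-/-, described as biological replicates. Total RNA was extracted with a column kit and converted to biotinylated cRNA, per the labels. Every library was matched to its group by its title. The labels give neither litter, sex nor array position, and the Villin-Cre transgene is named for the mutants alone, so its own effect and that of the Prdm1 alleles cannot be separated by these groups.

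The deposited table of raw values gives 1 linear intensity per probe and array, with no background subtraction, beside a detection p-value per probe and array that the authors' software derived from negative control beads. GenomeStudio 2009.2 was used, per the submitters' processing notes. The steps of the detection p-values are 1 in 936. A second deposited table holds processed intensity values. Each of its columns was a straight-line function of the raw column of the same array, with a largest residual of 0.011 intensity units, a constant background subtracted and 1 scale factor from 0.754 to 1.38 per array, with column medians from 4.81 to 6.98. Its scale is linear and its direction that of brightness, with no centring of genes. The name of its normalisation is not given in the sources used here. Raw medians per array ran from 56.6 to 79.7, and correlations between normalised arrays from 0.939 to 0.989, so no pair of arrays held identical values. These correlations cannot tell repeated arrays of the same RNA from separate embryos, which rest on the labels.

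The main values were made from the raw table with neqc in limma 3.58.1 under R 4.3.3. It fits the normexp background model on the detection p-values, adds an offset of 16, normalises between arrays by quantiles and takes log2. The offset draws fold changes of dim probes towards 1. A probe was tested if its detection p was under 0.01 on at least 5 of 21 arrays, which left 16641 of 45281 probes. The platform annotation gave 1 gene symbol for 34885 probes and several for 18, and 10378 probes were unnamed in it. The symbols of 34807 probes were matched through their gene number to the RefSeq gene table of the mouse build GRCm38. Of the probes tested, 2170 carried no single symbol, and 367 of those changed. The gene of a symbol was represented by its tested probe with the highest mean, giving 9961 genes. Of 144 named genes 47 had a further tested probe, and of 64 such probes 5 had the opposite sign, in no case with both probes past the threshold, and 11 a different call.

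Groups were compared with lmFit and eBayes, with genotype as the only term, and Benjamini-Hochberg adjustment over all probes tested. A gene was called changed at an adjusted p under 0.05. Where a probe was not detected on any array of a group, or for a changed named gene on the minority of them, the difference is a bound, written as at least N-fold. It is the mean of the brighter group over all its arrays against the mean of, per array, the higher of the lowest signal among detected probes and the dim probe's own signal. Permutation tests were two-sided with 100000 draws, and the smallest p they can give is 1e-05. The programme scores were the mean over a list's members of log2 intensity centred on all samples. The change in spread was tested with 100 permutations.

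Gene lists were fixed before the data were examined, as were the tests, the alternatives and the rule for naming genes. Of each list, at least 5 members had to be tested, and all 39 lists passed. They cover enterocyte programmes, metabolism, the epithelial cell types, stress and interferon responses, and markers of the other tissues that a dissection could bring. The main test was camera with a preset correlation between genes of 0.01, which compares a list with all other genes; camera with an estimated correlation and fry were alternatives. The named genes were Prdm1; the 14 largest rises and the 14 largest falls among changed genes; Sis, Treh, Arg2, Lct, Ass1, Asl, Cps1, Fcgrt, Glb1, Lyz1, Vil1, Lgr5, Muc2 and Chga whatever their result; and from each list up to 4 changed members with the largest absolute difference, or, where none changed, the 2 with the smallest p. Mgam and Mki67 were also on that rule and were not among the genes tested. Genes from closely related families, such as Gsta, Cyp2d, Reg3 and Slc5a4, are uncertain, since probes can read relatives.

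The fit was tested on simulated data for the 9961 genes with 200 changed genes. Of 50 genes changed by 0.5 log2, 40 were recovered, and all 50 were at 1, 1.5 and 2 log2. Of 205 genes called, 15 were false. Of the simulated lists, the shifted one was called and no unchanged one was, but that simulation held independent genes. Alternatives changed 1 choice at a time, except that the deposited processed values with a floor of 16 before log2 differ in background, scaling and offset together. The others were no background correction, median scaling, no filter on dim probes, a stricter filter of 10 arrays, replicate numbers as a fixed or a random block, a trended and robust variance, array weights, Xist as a covariate, the mean of a gene's probes, other list tests, and leaving out each sample. Added after seeing the data were the number of detected probes as a covariate, the side of the samples on their leading axis as a block, fits within each side, a fit without 6 libraries with colon markers, and the count of splits per list. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15. Genes were ordered by distance from Prdm1 with the start positions of the gene table, and the probes themselves were not matched to a genome.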

Results

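Gene expression was measured in the small intestine of mouse embryos at day E18.5. The series compared 11 libraries labelled Prdm1+/+ with 10 labelled Prdm1-/-, each a separate biological replicate by its label and each hybridised to 1 Illumina WG6_V2 bead array. Prdm1 encodes Blimp1, a zinc finger repressor of transcription. By the labels, the mutants carried the Villin-Cre transgene, which acts in intestinal epithelium, together with the CA and BEH alleles of Prdm1, and the controls carried 1 CA allele and 1 wild-type allele. The strain background was mixed. Of 45281 probes, 14596 to 16085 were detected on an array, with means of 15294 ± 479 (SD, n = 11) in the controls and 15250 ± 537 (SD, n = 10) in the mutants. The number of arrays limits the precision of every value.

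The targeted gene was examined first, since it can check the labels. One Prdm1 probe was not detected on any of the 11 control arrays (4.55 ± 0.22 log2 intensity, SD, n = 11) and was detected on all 10 arrays labelled Prdm1-/- (7.99 ± 0.59, SD, n = 10). Its signal was at least 7.31-fold higher in the libraries labelled Prdm1-/- (limma adjusted p = 1.64e-12; two-sided permutation p = 3e-05). A second Prdm1 probe was not detected on any array. It read 4.39 in labelled controls and 4.31 in labelled mutants (-0.09, two-sided permutation p = 0.002). As both means lie below detection, no direction is read from it. The rise of the first probe goes against a simple loss of the transcript. Where that probe lies relative to the altered part of the gene is not given in the sources used here, so it does not check the deletion. The groups are therefore called labelled controls and labelled mutants throughout, and every direction below rests on those labels. Differences are log2 intensity in labelled mutants minus labelled controls ± SE from limma, with n = 10 and n = 11, and adjusted p-values are Benjamini-Hochberg values over all 16641 probes tested.

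**Figure D1:**
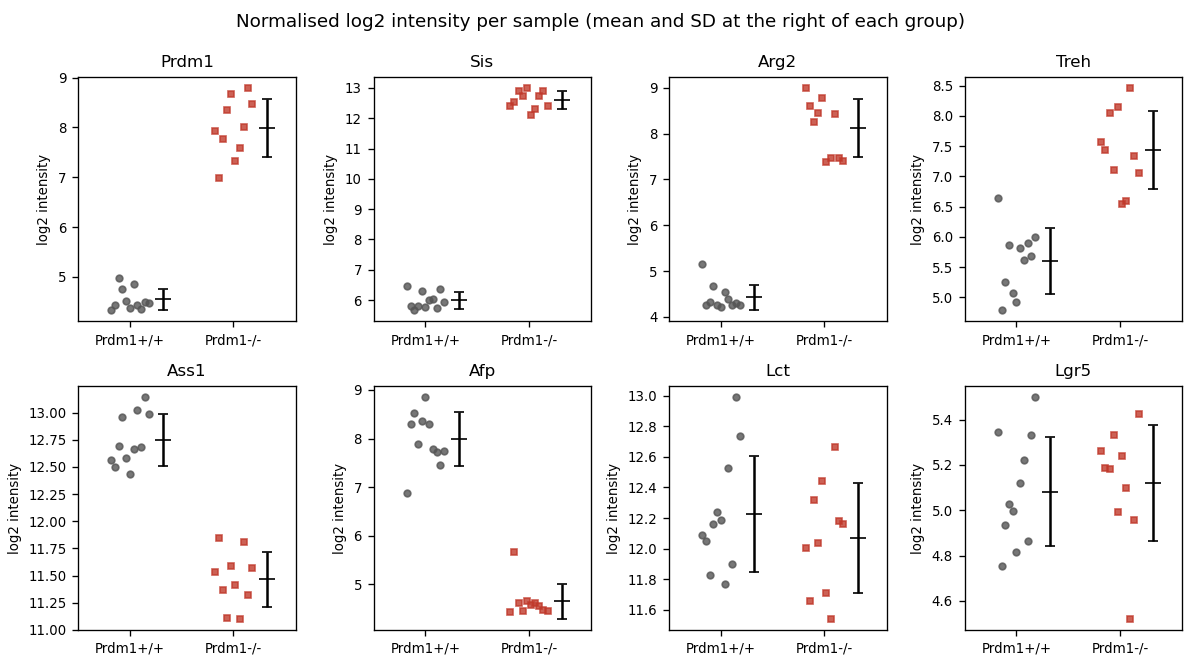
Normalised log2 intensity (vertical axes) of 8 genes in each labelled control (grey circles, n = 11) and labelled mutant (red squares, n = 10), with the mean and SD beside each group. Prdm1, Sis and Arg2 show no overlap between groups, with Sis means of 5.99 and 12.61, whereas Lct (12.23 and 12.07) and Lgr5 (5.08 and 5.12) overlap throughout. Lgr5 was detected on 4 control and 5 mutant arrays only.

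The comparison of the groups asks how the embryonic intestinal transcriptome differs with the Prdm1 genotype. By the labels, only the mutants carried the BEH allele, so effects in the epithelium and in other cells cannot be separated in whole tissue. The largest rise was that of Sis, which encodes the sucrase-isomaltase of the brush border. It was 98.3-fold higher in labelled mutants, from 5.99 ± 0.28 to 12.61 ± 0.29 log2 intensity (difference 6.62 ± 0.12, adjusted p = 2.05e-21). Cyp4v3, of the fatty acid hydroxylase family of cytochromes P450, rose 20.1-fold (4.33 ± 0.13), the water and glycerol channel gene Aqp3 rose 12.3-fold (3.63 ± 0.15) and Slc16a5, of the monocarboxylate transporter family, rose 10.2-fold (3.35 ± 0.11). Arg2, the mitochondrial arginase, was not detected in any labelled control and was at least 8.05-fold higher in labelled mutants (adjusted p = 2.2e-12). The fetal albumin-like protein gene Afp had the largest fitted fall. It was detected in all 11 labelled controls and in 1 of 10 labelled mutants, and was at least 7.04-fold lower there (adjusted p = 1.03e-11).

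Among the other large rises were 2210407C18Rik (15.2-fold), Gsta1 (12.3-fold), 1810065E05Rik (at least 5.69-fold, detected in 1 of 11 labelled controls, and treated further at the colon markers), Gsta4 (7.06-fold), Cyp2j13 (6.82-fold, detected in 6 of 11 labelled controls), Eci3 (5.85-fold), the antimicrobial lectin gene Reg3b (5.48-fold) and Gsta2 (5.43-fold). The other large falls included transthyretin (Ttr, 5.78-fold lower), apolipoprotein M (Apom, 5.69-fold), Fndc5 (5.09-fold), transferrin (Trf, 4.4-fold), the keratin gene Krt23 (4.36-fold) and the sugar phosphate exchanger gene Slc37a2 (4.23-fold). Pgam2 fell 4.14-fold, Fam167a 4.01-fold and Lrrn1 3.99-fold. Gastric lipase (Lipf), coagulation factor IX (F9) and Gm14685, detected in 1, 1 and 2 of the 10 labelled mutants, were at least 3.35-fold, 3.25-fold and 3.07-fold lower. Cysrt1, detected in 6 labelled mutants, fell 4.03-fold. The largest adjusted p among the 14 largest rises, Prdm1 included, and the 14 largest falls was 2.19e-07, that of Reg3b. Gsta and Cyp2 genes have close relatives, so a probe may read more than 1 of them.

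In total, 2307 of 9961 genes tested changed at an adjusted p under 0.05 (23.2%), of which 1054 were higher and 1253 lower in labelled mutants. The median absolute difference of the changed genes was 0.37 log2. A change of at least 2-fold was measured for 210 genes, 104 higher and 106 lower, and in 162 of these no labelled mutant overlapped any labelled control. Over all genes tested, 438 showed no overlap, against a chance share of 0.000567% per gene. With each array scaled to a common median instead of quantile normalisation, 462 genes were higher and 1252 lower, so that the larger number of falls depended in size on the scaling. Without background correction 117 genes reached 2-fold.

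Enterocyte genes that rise around weaning were tested as a list fixed in advance, drawn from general knowledge to which studies of Prdm1 mutants contributed, so it is not fully independent of this question. In this list 5 of 9 measured members rose, 1 fell and 3 did not pass (5 and 1 adjusted over the list alone). Besides Sis and Arg2, the trehalase gene Treh rose 3.57-fold (1.84 ± 0.24, adjusted p = 3.74e-06) and ketohexokinase (Khk) rose 2-fold (1.00 ± 0.12). Lyz1, a lysozyme gene, fell (-0.54 ± 0.09, adjusted p = 1.47e-04). Within the samples called part A below, Lyz1 differed by -0.30 and did not pass (limma adjusted p = 0.16). The median of the list was 0.63 log2, or 0.19 with genes undetected in a group at their bound, and camera gave an adjusted p of 8.71e-04 with the preset correlation and an adjusted p of 0.249 with an estimated correlation. Per embryo, the mean centred level of the 9 genes was -0.69 ± 0.19 (SD, n = 11) in labelled controls and 0.76 ± 0.30 (SD, n = 10) in labelled mutants, a difference of 1.45 with no overlap (two-sided permutation p = 3e-05). The difference was 1.34 with undetected genes at their bound. Sis (6.62) and Arg2 (fitted 3.70) weigh most in this mean, so the score largely restates them. A score without them was not computed.

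Enterocyte genes of the suckling period moved the other way: 1 of 15 measured members rose, 12 fell and 2 did not pass (1 and 12 adjusted over the list alone). This list was drawn from the same general knowledge as the weaning list, so the same limit on its independence applies. Argininosuccinate synthase (Ass1) fell 2.44-fold (-1.28 ± 0.11, adjusted p = 2.75e-09), argininosuccinate lyase (Asl) 2.29-fold (-1.20 ± 0.17), the neonatal Fc receptor gene Fcgrt 1.82-fold (-0.87 ± 0.12) and beta-galactosidase (Glb1) 1.7-fold (-0.77 ± 0.08). Afp, named above, is a member and had the largest fall of the list. The endocytic receptor gene Lrp2 fell 3.36-fold (-1.75 ± 0.23). The folate transporter gene Slc46a1 rose 3.77-fold (1.91 ± 0.20), and lactase (Lct) differed by -0.15 ± 0.15, which did not pass (adjusted p = 0.554). For this list, camera gave an adjusted p of 5.38e-09 with the preset correlation and an adjusted p of 0.00351 with an estimated correlation. The score per embryo of the 15 genes was 0.38 ± 0.11 (SD, n = 11) in labelled controls and -0.42 ± 0.11 (SD, n = 10) in labelled mutants, a difference of -0.80 with no overlap (two-sided permutation p = 3e-05).

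**Figure D2:**
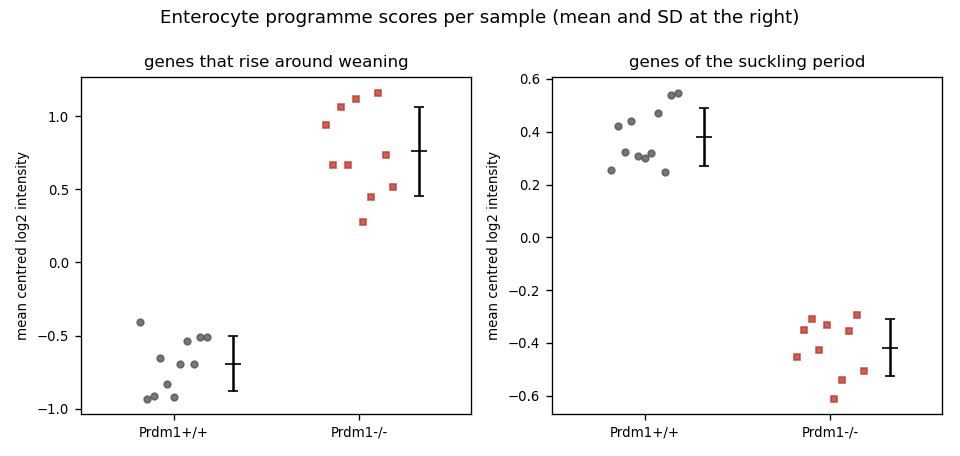
Mean centred log2 intensity per embryo (vertical axes) of the genes that rise around weaning (left) and of the genes of the suckling period (right), in labelled controls (grey circles, n = 11) and labelled mutants (red squares, n = 10), with the mean and SD beside each group. The groups do not overlap in either score, and the differences are 1.45 and -0.80. Sis and Arg2 weigh most in the left score.

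Genes of lysosomal enzymes and the endocytic apparatus fell together. In that list 0 of 29 measured members rose, 21 fell and 8 did not pass (0 and 24 adjusted over the list alone). Legumain (Lgmn) fell 3.9-fold (-1.96 ± 0.14, adjusted p = 2.92e-10), beta-glucuronidase (Gusb) 2.91-fold (-1.54 ± 0.09) and cathepsin H (Ctsh) 2.73-fold (-1.45 ± 0.13), while Amn, a partner of cubilin, fell by less (-0.36 ± 0.06). The list median was -0.58 log2, and camera gave an adjusted p of 3.3e-15 with the preset correlation and an adjusted p of 0.0117 with an estimated correlation. Several members are shared with the suckling list. Lysosomal enzymes such as Lgmn and Ctsh are abundant in macrophages as well, and the macrophage receptor gene Csf1r fell too (below), so the cells in which these transcripts fell are not known from whole tissue.

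In arginine and urea cycle metabolism, 2 of 16 measured members rose, 8 fell and 6 did not pass (2 and 9 adjusted over the list alone). Beside Ass1 and Asl, carbamoyl phosphate synthase (Cps1) fell 1.47-fold (-0.55 ± 0.09, adjusted p = 4.13e-05), whereas Arg2 and glutamate dehydrogenase (Glud1, 2.42-fold, 1.28 ± 0.10) rose. The list shifted down, and camera gave an adjusted p of 0.00935 with the preset correlation and an adjusted p of 0.186 with an estimated correlation. Without the 6 libraries with colon markers described below the preset adjusted p was 0.107. In carbohydrate digestion and sugar handling, 6 of 15 measured members rose, 0 fell and 9 did not pass (7 and 0 adjusted over the list alone). The sodium-coupled transporter family gene Slc5a4b rose 2.83-fold (adjusted p = 8.9e-12), and its relative Slc5a4a, not detected in labelled controls, was at least 1.56-fold higher. The list shifted up, and camera gave an adjusted p of 1.65e-04 with the preset correlation and an adjusted p of 0.249 with an estimated correlation. Its median was 0.09 log2, and -0.01 with median scaling.

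Xenobiotic metabolism genes rose: 15 of 23 measured members rose, 1 fell and 7 did not pass (18 and 1 adjusted over the list alone). Beside the 3 Gsta genes, Cyp2d26 rose 4.72-fold (2.24 ± 0.13, adjusted p = 1.4e-11). For this list, camera gave an adjusted p of 2.11e-10 with the preset correlation and an adjusted p of 0.0235 with an estimated correlation. In the oxidative phosphorylation list 22 of 46 measured members rose, 0 fell and 24 did not pass (26 and 0 adjusted over the list alone). The changes were small, as in Ndufa4 (0.50 ± 0.09), Ndufb9 (0.42 ± 0.12), Ndufb5 (0.35 ± 0.09) and Cyc1 (0.33 ± 0.07), and with median scaling 1 of the 46 members rose. There, camera gave an adjusted p of 7.29e-08 with the preset correlation and an adjusted p of 0.109 with an estimated correlation. In hypoxia and glycolysis, 13 of 20 measured members rose, 0 fell and 7 did not pass (14 and 0 adjusted over the list alone), among them carbonic anhydrase 9 (Car9, 2.05-fold, 1.04 ± 0.14), aldolase A (Aldoa, 0.54 ± 0.06), Pdk1 (0.45 ± 0.08) and Pgam1 (0.42 ± 0.06). With median scaling 6 of 20 rose. For that list camera gave an adjusted p of 1.13e-06 with the preset correlation and an adjusted p of 0.249 with an estimated correlation.

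Interferon-stimulated genes shifted up, with 12 of 31 members higher, 2 lower and 17 not past the threshold (14 and 3 adjusted over the list alone). Ifit3 rose 2.95-fold (1.56 ± 0.35, adjusted p = 0.00181), Oasl1 2.84-fold (1.51 ± 0.30), Usp18 2.77-fold (1.47 ± 0.26) and Oasl2 2.6-fold (1.38 ± 0.25), and camera gave an adjusted p of 0.00323 with the preset correlation and an adjusted p of 0.726 with an estimated correlation. The list scores overlapped, from -0.66 to 0.47 in labelled controls and -0.13 to 0.62 in labelled mutants. Controls 8 to 11 were the highest controls. Within the samples called part B below, Ifit3 differed by 1.49 and did not pass (limma adjusted p = 0.0752). In the unfolded protein response list 2 of 18 measured members rose, 9 fell and 7 did not pass (3 and 11 adjusted over the list alone). The members went both ways: the chaperone cofactor gene Sdf2l1 (-0.69 ± 0.15) and Sel1l (-0.49 ± 0.06), of endoplasmic reticulum degradation, fell, whereas Trib3 (1.02 ± 0.11) and asparagine synthetase (Asns, 0.75 ± 0.10) rose. The list shifted down, and camera gave an adjusted p of 0.0205 with the preset correlation and an adjusted p of 0.425 with an estimated correlation. Without the 6 libraries with colon markers the preset adjusted p was 0.314.

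Markers of other tissues moved in part. Of the liver markers, 0 of 11 measured members rose, 5 fell and 6 did not pass (0 and 6 adjusted over the list alone). The fallen ones included Ttr and Trf, fibrinogen alpha (Fga, 3.54-fold, -1.82 ± 0.19) and Itih3 (at least 2.6-fold, detected in 2 of 10 labelled mutants), all of which encode secreted plasma proteins. The list shifted down, and camera gave an adjusted p of 1.15e-05 with the preset correlation and an adjusted p of 0.177 with an estimated correlation. Albumin, the most abundant hepatocyte product, was not detected on any of the 21 arrays. Labelled controls 8, 9 and 11 stood apart in the liver score (below). Albumin was silent there too, although the liver marker Ahsg was high, so its absence excludes no liver RNA. Of the mesenchyme markers, 2 of 17 measured members rose, 0 fell and 15 did not pass (2 and 0 adjusted over the list alone), the risers being collagens (Col3a1, 0.52 ± 0.13, and Col5a1, 0.29 ± 0.09), neither of which passed with median scaling. There, camera gave an adjusted p of 0.033 with the preset correlation and an adjusted p of 0.337 with an estimated correlation, and without control 9 or without mutant 6 the adjusted p with the preset correlation was 0.0582 or 0.0504. Within the samples called part B below it was 0.0655. Without the 6 libraries with colon markers it was 0.25, and Col5a1 differed by 0.10 (adjusted p = 0.628). Of the immune cell markers, 1 of 15 measured members rose, 4 fell and 10 did not pass (1 and 6 adjusted over the list alone). The macrophage receptor gene Csf1r fell 2.79-fold (-1.48 ± 0.10, adjusted p = 2.37e-10), Lyz2 (-0.59 ± 0.18) and Cd52 (-0.36 ± 0.09) fell by less, and Mrc1 rose (0.30 ± 0.10). Second probes of Lyz2 (-0.25, adjusted p = 0.0883) and Cd52 (-0.28, 0.486) did not pass. The rise of Mrc1 did not pass with median scaling (adjusted p = 0.197), nor did Lyz2 within the samples called part A below (-0.26, 0.210). For this list, camera gave an adjusted p of 0.0147 with the preset correlation and an adjusted p of 0.455 with an estimated correlation. Within part A the preset adjusted p of the list was 0.335.

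**Figure D3:**
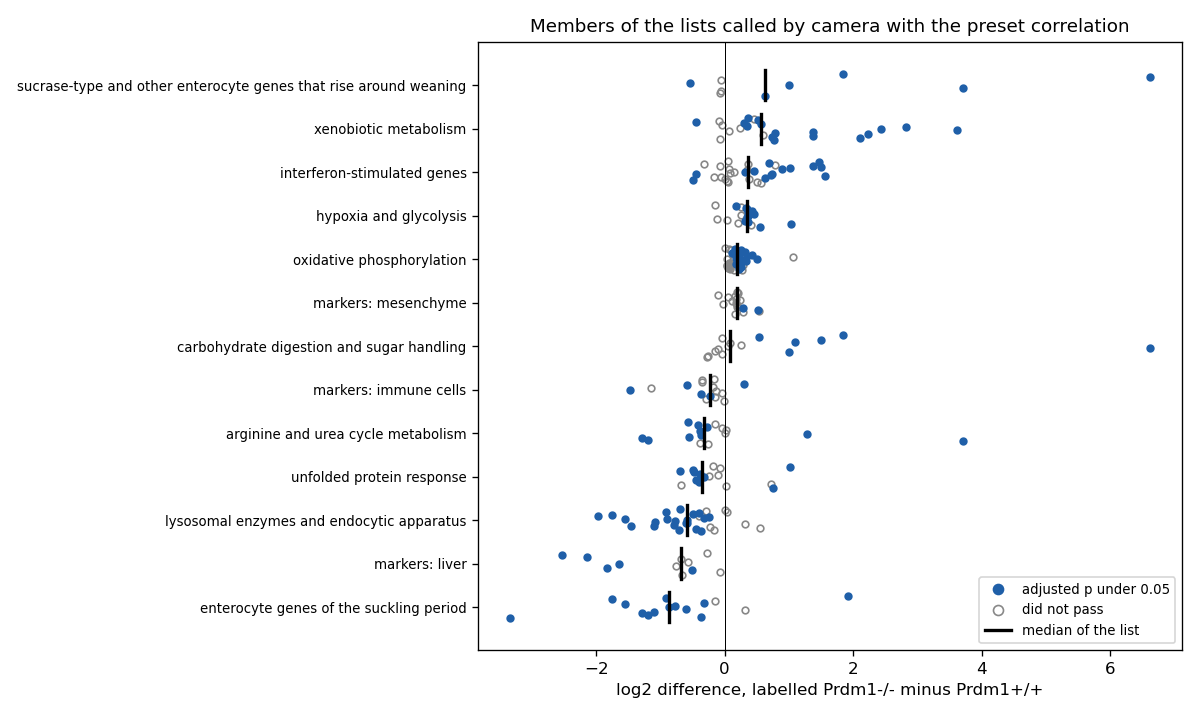
Log2 differences (horizontal axis, labelled mutant minus labelled control) of the members of the 13 called lists, one row per list, with filled points for members at an adjusted p under 0.05, open points for the rest and a bar at the list median. Lysosomal and suckling members lie mostly below 0 (medians -0.58 and -0.87) and xenobiotic members mostly above (median 0.57).

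Of 39 lists, camera with a preset correlation called 13, of which 7 shifted up and 6 down. The calls of the suckling, lysosomal and xenobiotic lists held with an estimated correlation and those of the other 10 did not. In 100 splits of the samples, the real one included, 20 called at least 13 lists, so the number of called lists was not larger than regrouped samples gave. A camera p as small as the real one was reached in 1 split for the suckling list, 1 for the lysosomal list and 1 for the xenobiotic list, which is the real split itself in each case. It was reached in 4 splits for the weaning list, 5 for oxidative phosphorylation, 6 for arginine metabolism, 8 for carbohydrate digestion, 8 for liver markers and 9 for hypoxia and glycolysis. The figures were 15 for the unfolded protein response, 19 for mesenchyme, 23 for immune cells and 41 for interferon-stimulated genes.

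Other epithelial lists held large changes of single genes in both directions and were not called. Brush border and peptide transport genes (6 higher and 4 lower of 19, 6 and 7 adjusted over the list alone, camera adjusted p = 0.93) included the glutamate transporter gene Slc1a1 (1.84 ± 0.15), brush border myosin Myo1a (1.15 ± 0.11), enteropeptidase (Tmprss15, at least 2.21-fold, detected in 5 of 11 labelled controls) and villin (Vil1, 0.64 ± 0.09), which rose, and the protease meprin alpha (Mep1a, -0.88 ± 0.12), which fell. Junction and keratin genes (7 higher and 8 lower of 26, 7 and 10 adjusted over the list alone, camera adjusted p = 0.973) included Cldn1, detected in all 11 labelled controls and in no labelled mutant and at least 2.17-fold lower there, and Krt20 (1.47 ± 0.13) and Krt19 (0.92 ± 0.07), which rose. Of epithelial transcription factors (3 higher and 6 lower of 24, 4 and 6 adjusted over the list alone, camera adjusted p = 0.829), Bcl6 (2.82-fold) and Tfcp2l1 (-0.75 ± 0.11) fell and Pparg (0.80 ± 0.07) and Klf5 (0.58 ± 0.08) rose. Lipid absorption (3 higher and 8 lower of 23, 4 and 10 adjusted over the list alone, camera adjusted p = 0.11) held a rise of the fatty acid transport gene Slc27a2 (1.51 ± 0.21) and the sterol transporter gene Abcg5 (0.77 ± 0.15) and a fall of the lipid droplet genes Plin2 (-0.73 ± 0.07) and Cidec (-0.65 ± 0.12). The list was called as shifted down with median scaling (adjusted p = 0.0495), without the filter on dim probes (0.0455) and within part A (0.0152). Bile acid genes (1 higher and 3 lower of 8, 1 and 3 adjusted over the list alone, camera adjusted p = 0.141) held a rise of Abcc3 (1.49 ± 0.17) and falls of the bile salt pump gene Abcb11 (-1.05 ± 0.12), the receptor gene Nr1h4 (-0.48 ± 0.06) and Abcc2 (-0.59 ± 0.10, of which a second probe did not pass).

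Fatty acid oxidation genes (5 higher and 2 lower of 18, 5 and 3 adjusted over the list alone, camera adjusted p = 0.274) included Pdk4 (0.78 ± 0.14), Angptl4 (0.46 ± 0.09), Acadvl (0.38 ± 0.06) and Cpt2 (0.36 ± 0.07). Cholesterol synthesis genes (0 higher and 3 lower of 17, 0 and 3 adjusted over the list alone, camera adjusted p = 0.629) included small falls of Sc5d (-0.33 ± 0.09), Mvd (-0.34 ± 0.11) and Fdps (-0.29 ± 0.10). A second Fdps probe did not differ past the threshold (-0.057, adjusted p = 0.855), and the mean of both gave -0.17 (0.148). On leaving out 1 library, Fdps lost its call in 14 fits and Mvd in 9, and neither Sc5d, Mvd nor Fdps passed within part A or B. In the Paneth cell and antimicrobial list (2 higher and 1 lower of 11, 2 and 1 adjusted over the list alone, camera adjusted p = 0.629), Reg3a was not detected in labelled controls and was at least 3.41-fold higher in labelled mutants, beside Reg3b, its close relative. Goblet cell genes (4 higher and 1 lower of 15, 4 and 1 adjusted over the list alone, camera adjusted p = 0.225) included a fall of Zg16 (-0.97 ± 0.28) and rises of Klk1 (0.45 ± 0.15), Sytl2 (0.31 ± 0.07) and Slc12a8 (0.28 ± 0.06). These 3 rises did not pass with median scaling (adjusted p = 0.186, 0.134 and 0.177). Without the 6 libraries with colon markers described below, Zg16 differed by -0.45 (adjusted p = 0.483). The mucin gene Muc2 did not pass (0.16 ± 0.28). Of enteroendocrine genes (1 higher and 2 lower of 22, 1 and 1 adjusted over the list alone, camera adjusted p = 0.973), Gip (-0.76 ± 0.15) and Sct (-0.24 ± 0.08) fell, Pax4 was detected in 5 labelled mutants and no labelled control, and Chga did not pass (-0.06 ± 0.10). Of tuft cell genes (1 higher and 1 lower of 5, 1 and 1 adjusted over the list alone, camera adjusted p = 0.629), Hpgds, detected in 10 labelled controls and 3 labelled mutants, was at least 1.29-fold lower. Dclk1 was detected in 1 labelled control and 4 labelled mutants, so that no size is given.

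Stem cell and Wnt target genes (2 higher and 0 lower of 11, 2 and 0 adjusted over the list alone, camera adjusted p = 0.123) held small rises of Cdca7 (0.27 ± 0.06) and Cd44 (0.25 ± 0.08). Neither passed with median scaling (adjusted p = 0.269 and 0.284). A second Cd44 probe did not pass (0.18, adjusted p = 0.147), and without the 6 libraries with colon markers Cd44 differed by 0.13 (0.572). The list was called as shifted up within part A (adjusted p = 0.0191). The stem cell gene Lgr5 did not pass (0.04 ± 0.11, adjusted p = 0.857). Its probe was detected on only 4 of 11 control and 5 of 10 mutant arrays, so a difference could be missed. Proliferation genes (0 higher and 1 lower of 26, 0 and 0 adjusted over the list alone, camera adjusted p = 0.629) included 1 small fall, of Mcm2 (-0.25 ± 0.08). Antigen presentation genes (3 higher and 1 lower of 26, 2 and 0 adjusted over the list alone, camera adjusted p = 0.816) included Psmb10 (0.35 ± 0.08), Tap1 (0.37 ± 0.12) and H2-T23 (0.53 ± 0.15), which rose, and Cd74 (-0.37 ± 0.13), which fell and of which 1 of 2 other probes did not pass (adjusted p = 0.083). With median scaling Mcm2, Tap1 and H2-T23 did not pass (adjusted p = 0.102, 0.0911 and 0.0605). Immediate-early and heat shock genes (1 higher and 1 lower of 18, 1 and 1 adjusted over the list alone, camera adjusted p = 0.973) included a fall of Zfp36 (-0.34 ± 0.07) and a rise of Klf6 (0.26 ± 0.08). Klf6 did not pass with median scaling (0.18, adjusted p = 0.227), and without the 6 libraries with colon markers it differed by 0.13 (0.513). Of 10 housekeeping genes (2 higher and 1 lower of 10, 2 and 1 adjusted over the list alone, camera adjusted p = 0.973), Gusb, which is also lysosomal, fell, and Gapdh (0.31 ± 0.05) and Pgk1 (0.34 ± 0.08), which are also glycolytic, rose. With median scaling the rise of Pgk1 did not pass.

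Among cell and tissue markers, smooth muscle (0 higher and 0 lower of 12, 0 and 0 adjusted over the list alone, camera adjusted p = 0.816), red blood cells (0 higher and 0 lower of 5, 0 and 0 adjusted over the list alone, camera adjusted p = 0.572), stomach (0 higher and 0 lower of 5, 0 and 0 adjusted over the list alone, camera adjusted p = 0.876) and sex-linked transcripts (0 higher and 0 lower of 7, 0 and 0 adjusted over the list alone, camera adjusted p = 0.992) held no changed member. Their members with the smallest p were Myocd (0.18 ± 0.13) and Acta2 (0.08 ± 0.07), Slc4a1 (-0.53 ± 0.25) and Hba-a1 (-0.19 ± 0.14), Ctse (-0.35 ± 0.19) and Sostdc1 (0.20 ± 0.11), and Uty (-0.12 ± 0.09) and Ddx3x (0.18 ± 0.15). None of these passed, and 2 other Ctse probes were higher in labelled mutants (1.01 and 0.55 log2, adjusted p = 0.0378 and 0.0389). In the endothelium list (0 higher and 1 lower of 14, 0 and 0 adjusted over the list alone, camera adjusted p = 0.805) Plvap fell (-0.37 ± 0.12), and in the pancreas list (0 higher and 1 lower of 17, 0 and 1 adjusted over the list alone, camera adjusted p = 0.572) Cela1 fell (-1.31 ± 0.31). Cela1 differed by -0.86 without the 6 libraries with colon markers (limma adjusted p = 0.1755) and by -0.86 within part A (0.325). Enteric neuron and glia markers (3 higher and 1 lower of 10, 4 and 1 adjusted over the list alone, camera adjusted p = 0.141) included a fall of Ret (-0.52 ± 0.07) and rises of Uchl1 (0.39 ± 0.12), Vip (0.32 ± 0.11) and Stmn2 (0.31 ± 0.10). With median scaling none of these 3 rises passed (adjusted p = 0.0511, 0.169 and 0.241). Without the 6 libraries with colon markers Uchl1 differed by 0.23 (adjusted p = 0.447), Vip by 0.34 (0.165) and Stmn2 by 0.094 (0.748). Markers of the proximal small intestine (1 higher and 4 lower of 13, 2 and 4 adjusted over the list alone, camera adjusted p = 0.274) included Cybrd1 (-0.56 ± 0.08) and Rbp2 (-0.32 ± 0.09), which fell, and Bco1, detected in 5 labelled mutants and in no labelled control (at least 1.1-fold higher). Without the same 6 libraries Rbp2 differed by -0.17 (adjusted p = 0.340), and a second Rbp2 probe did not pass (0.0648). Those of the distal small intestine (1 higher and 3 lower of 14, 1 and 3 adjusted over the list alone, camera adjusted p = 0.255) included Nox4 (-1.59 ± 0.11), which fell, and Osr2 (0.77 ± 0.11), which rose. A second Osr2 probe had the opposite sign and did not pass (-0.13, limma adjusted p = 0.913), and the mean of the probes gave 0.32 (0.49). Of colon markers (2 higher and 1 lower of 5, 2 and 1 adjusted over the list alone, camera adjusted p = 0.973), Aqp8 fell (-1.58 ± 0.16), while Car1 and Hoxd10 were detected in the same 6 labelled mutants and in no labelled control, at least 1.58-fold and 1.44-fold higher. Without these 6 libraries 1251 genes changed, and the arginine, unfolded protein response and mesenchyme lists were not called (adjusted p = 0.107, 0.314 and 0.25). That fit held 4 labelled mutants against 11 labelled controls, so calls can be lost through fewer samples alone. In that fit fatty acid oxidation was called as shifted up (adjusted p = 0.0105). The riser 1810065E05Rik read 8.09 to 9.19 log2 intensity in these 6 libraries and 6.11 to 6.71 in the other 4 labelled mutants. Without the 6 its fitted difference was 1.95 log2 rather than 3.19. In 9 of the uncalled lists, brush border genes among them, the median, the mean and the test differed in sign.

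The spread between embryos was compared as well. The median log2 ratio of the SD in labelled mutants to that in labelled controls was 0.10 over 16641 probes, which did not differ from permuted labels (permutation p = 0.39, 100 draws). With median scaling it was 0.26 (p = 0.04). Within both groups the samples lay apart on a leading axis of deviations from the group means that carried 32.3% of the within-group variance. On one side were 6 labelled controls and 4 labelled mutants (part A) and on the other 5 labelled controls and 6 labelled mutants (part B). The arrays of part A had 14869 ± 202 (SD, n = 10) detected probes and those of part B 15641 ± 377 (SD, n = 11). Within part A 1375 genes changed between the labelled groups and within part B 1230, and 2835 changed with the part as a block, a count raised in part by construction, as the parts came from the same residuals. The weaning score differed by 1.30 within part A and 1.54 within part B, and the suckling score by -0.82 and -0.80. No probe differed between the parts in its response at a limma adjusted p under 0.05. An unadjusted p under 0.05 was found for 342 of 16641 probes, against 832 expected by chance. The parts were drawn from these same values, along an axis shared by both groups. These counts therefore cannot show that both parts responded alike.

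**Figure D4:**
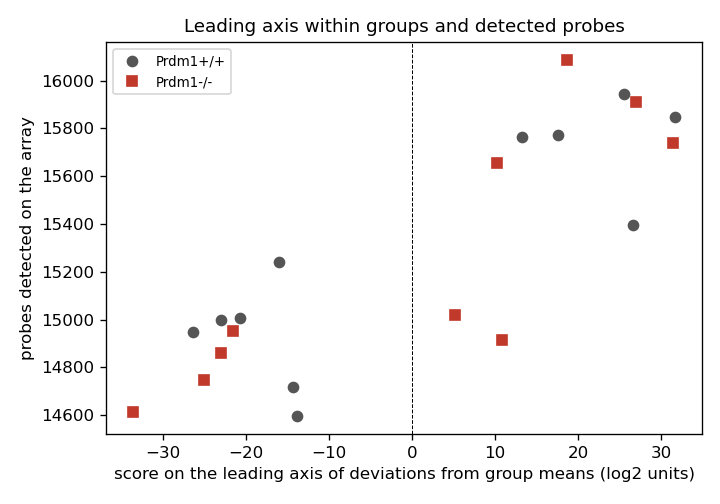
Score on the leading axis of deviations from the group means (horizontal axis, log2 units) against the number of probes detected on the array (vertical axis) for labelled controls (grey circles, n = 11) and labelled mutants (red squares, n = 10). Samples of both groups lie on both sides of 0, with detected probes averaging 14869 on the left and 15641 on the right.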

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

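Of 183 sets of labelled mutant values (144 named genes and 39 list scores), 18 held 1 embryo far from the other 9, against about 1 in 20 by chance (9.84% observed). The labelled controls, with 11 samples, were not tested in this way. Control 1 nevertheless lay nearest the labelled mutants in several of the largest changes. Arg2 read 5.15 there against 4.22 to 4.67 in the other controls, and Aqp3 6.65 against 5.25 to 6.05. Apom read 8.45 against 9.19 to 9.77, and Afp 6.88 against 7.46 to 8.85. Its weaning score of -0.40 was the highest of the controls. In Fndc5 (8.02) and Slc37a2 (8.93) control 1 lay inside the range of the other controls. The 3 tests on Prdm1 and the tests on other tissues and on immune cells were chosen after the result was seen. Values are log2 intensity of the embryo against the range of the other 9. In mutant 5, Ddx3x was 7.96 against 6.55 to 7.01, Pgk1 11.97 against 11.17 to 11.53, Bco1 7.03 against 4.42 to 5.81, Osr2 10.04 against 10.56 to 10.96 and Fga 5.79 against 6.62 to 7.55, and its hypoxia and glycolysis score was 0.66 against 0.00 to 0.24. In mutant 2, Afp was 5.66 against 4.43 to 4.65, Amn 12.73 against 12.36 to 12.50, Pgam2 6.24 against 5.30 to 5.80 and Klf5 12.21 against 12.52 to 12.86. In mutant 8, Itih3 was 5.86 against 4.57 to 5.16, Hba-a1 13.88 against 14.41 to 14.96 and Lgr5 4.52 against 4.96 to 5.43. Mutant 10 stood apart in Cps1 (12.45 against 11.66 to 11.95) and Cd74 (8.33 against 8.88 to 9.45), mutant 7 in Sostdc1 (6.44 against 5.18 to 5.83) and Pgam1 (9.17 against 9.31 to 9.46), and mutant 9 in the junction and keratin score (-0.15 against -0.05 to 0.05).

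Chance was weighed with 100 splits of the 21 samples into groups of 10 and 11, the real split included. For the 2307 changed genes 1 of 100 splits gave as many, the real one, and the highest of the others gave 1 gene, so chance is argued against. The smallest share that 100 splits can give is 1 in 100. The other splits mix the labelled groups, which raises the spread within them and lowers their counts. For the 210 genes changed at least 2-fold it was again 1 of 100, with 1 in the highest other split. For the 13 called lists chance cannot be excluded: 20 of 100 splits called as many, the highest other called 17 and the median of the others was 7.

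The rise of the Prdm1 probe in libraries labelled Prdm1-/- was set against 3 explanations. Single libraries exchanged between the groups are argued against, since 0 of 21 libraries lay on the other group's side in the Prdm1 signal or in the weaning score. An exchange of all labels between the groups stays open. Prdm1 was detected on 0 control arrays. Sis (5.99 in labelled controls and 12.61 in labelled mutants) and the weaning score, in which Sis weighs most, run the way the labels say. That holds only if unaltered fetal gut is low in genes that rise at weaning, which these data do not show. That the probe may read RNA that the altered allele still makes stays open too, as the other Prdm1 probe was detected on 0 of 21 arrays. A rise of transcription from the locus after loss of the protein, a biological explanation that the genotype offers, was not tested.

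The leading axis within groups parted 10 samples from 11, in both genotypes. Of 3299 genes with at least 2 detected probes, 30.7% had probes that differed from each other along the axis, against 0% along the second axis. A difference in RNA or labelling quality that acts on single probes predicts such differences. The axis was drawn from these same probes, and the second carried less of the within-group variance (9.14% against 32.3%). The contrast therefore cannot tell quality from a biological difference. Xist gave an example of probes that differed from each other. In the 12 libraries that carried its signal, 1 of 4 probes read 7.88 to 8.18 in part A and 5.24 to 6.48 in part B. Another read 8.19 to 9.91 in part A and 9.46 to 10.66 in part B. Pancreas, stomach, liver, colon or blood, each taken alone as the whole source, is argued against, since the best of these 5 marker scores left 5 of 21 samples on the wrong side. The stomach, colon and blood scores rest on 5 members each, which weakens that test for them, and it did not cover a mixture of tissues. A first form of that test, by correlation, had fallen at its bound and was replaced, so a smaller share stays open: pancreas scores deviated by 0.58 in part A and -0.53 in part B against an SD of 1.61. A different share of immune cells stays open: their score left 2 of 21 samples on the wrong side, the fewest of the 39 lists, at 0.14 in part A and -0.13 in part B against an SD of 0.22. Libraries with Xist signal numbered 6 in each part. No other biological explanation was tested.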

How the results depend on the processing

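The alternatives were fixed before the data were examined, except those on detected probes, on the parts of the samples and on the colon marker libraries, which were chosen after seeing the data. No list changed direction in a call. Of the named genes, Car1 (-0.067) and Hoxd10 (-0.11) turned in sign without the 6 colon marker libraries, all those with their signal. In every alternative that gave a value, 96 of the 143 named genes other than Prdm1 and 19 of 39 lists kept the same call. Those counts include genes and lists that passed in no fit, whose direction was not compared. Among the 13 called lists, only the suckling, lysosomal and xenobiotic lists kept their call throughout. The stricter filter gave no value for Bco1, Car1, Dclk1, Hoxd10, Lgr5 and Pax4 or for the tuft cell and colon lists. The number of changed genes ran from 1230 to 2835 over all alternatives. It was 1375 (552 higher, 823 lower) within part A, 1230 (529 higher, 701 lower) within part B and 1251 (556 higher, 695 lower) without the colon marker libraries, with fewer samples in each fit. Median scaling gave 462 higher genes and a variability ratio of 0.26 (p = 0.04, against 0.16 to 0.96 in the other alternatives with all or most samples and 0.14 to 0.68 on leaving out 1); the cause was not tested, and the median of all genes moved from 0.01 to -0.04 log2. Without background correction 117 genes reached 2-fold (65 higher, 52 lower), as unsubtracted background compresses differences. The number of called lists was 3 with an estimated correlation and 23 with fry, which does not compare a list with other genes. Calls of named genes were lost as follows. 5 were lost with the deposited values (Fdps, Klk1, Sct, Bco1, Rbp2). 1 was lost without background correction (Tap1). 21 were lost with median scaling (Cpt2, Mvd, Klk1, Sytl2, Slc12a8, Cdca7, Cd44, Mcm2, H2-T23, Tap1, Ndufb9, Ndufb5, Cyc1, Klf6, Col3a1, Col5a1, Uchl1, Vip, Stmn2, Mrc1, Pgk1). 15 were lost without the filter (Mvd, Fdps, Klk1, Sct, Cd44, Mcm2, Cd74, Tap1, Col5a1, Uchl1, Vip, Stmn2, Plvap, Lyz2, Mrc1). 7 were lost with the fixed replicate block (Mvd, Fdps, Sct, Cd44, Mcm2, Cd74, Uchl1). 3 were lost with the mean of the probes (Fdps, Cd52, Osr2). 33 were lost within part A (Lyz1, Tmprss15, Abcg5, Pdk4, Mvd, Sc5d, Fdps, Sytl2, Pax4, Sct, Hpgds, Mcm2, H2-T23, Cd74, Tap1, Ndufb9, Ndufb5, Cyc1, Klf6, Col3a1, Col5a1, Uchl1, Vip, Stmn2, Lyz2, Cd52, Mrc1, Cela1, Car1, Hoxd10, Bco1, Rbp2, Pgk1). 32 were lost within part B (Cidec, Mvd, Sc5d, Fdps, Zg16, Klk1, Slc12a8, Pax4, Sct, Dclk1, Cdca7, Cd44, Mcm2, Cd74, Tap1, Psmb10, Ifit3, Ndufb9, Ndufb5, Zfp36, Klf6, Col3a1, Col5a1, Vip, Stmn2, Plvap, Mrc1, Car1, Hoxd10, Bco1, Rbp2, Pgk1). Of the 27 lost without the colon marker libraries, 6 kept at least the same difference (Klk1, Sytl2, Slc12a8, Sct, Vip, Plvap), 15 kept 0.6 of it or more (Cidec, Mvd, Sc5d, Fdps, Dclk1, Cdca7, Cd74, Tap1, Sdf2l1, Col3a1, Uchl1, Lyz2, Cd52, Mrc1, Cela1) and 6 kept less (Zg16, Cd44, Klf6, Col5a1, Stmn2, Rbp2). The immune cell list lost its call within part A and the mesenchyme list within part B (adjusted p = 0.0655). Lipid absorption gained a call with median scaling and without the filter. Leaving out each sample in turn gave 2100 to 2339 changed genes, 198 to 216 of at least 2-fold, 12 or 13 lists, weaning scores of 1.41 to 1.51 and suckling scores of -0.81 to -0.78. In those fits 12 named genes near the threshold lost their call without at least 1 library, given here with the number of such libraries and the highest adjusted p: Cd44 (7, 0.0607 without Prdm1-/- replicate 6), Cd74 (13, 0.0732 without Prdm1-/- replicate 10), Fdps (14, 0.0869 without Prdm1-/- replicate 9), Klk1 (8, 0.0628 without Prdm1-/- replicate 6), Mcm2 (11, 0.0783 without Prdm1-/- replicate 7), Mrc1 (9, 0.0794 without Prdm1-/- replicate 4), Mvd (9, 0.0757 without Prdm1-/- replicate 7), Plvap (5, 0.057 without Prdm1-/- replicate 5), Sct (10, 0.0714 without Prdm1-/- replicate 5), Stmn2 (5, 0.0574 without Prdm1-/- replicate 9), Tap1 (12, 0.0721 without Prdm1-/- replicate 10), Vip (12, 0.0799 without Prdm1-/- replicate 7). With the replicate block, fixed, 2001 genes changed and 13 lists were called, and with the random one 2473 genes changed. Replicate numbers were not shown to pair the samples: same-numbered samples correlated at -0.25 to 0.30, and 0 controls correlated best with their own number. A weak pairing is not excluded, as 6 of 10 pairs were over 0.1 and the random block gave more changed genes than the main fit. The array block was not run, as the files give no array position. Scores were not tested with a variance model, weights or a random block, lists not with a random block or the robust variance, and the ratio of spreads not with these, a replicate block or gene means. Signal over background is the limit for many genes. Of 19057 symbols on the array, 9961 had a probe detected on 5 arrays, and without that filter 2034 genes changed.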

Other observations

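The 13 gene families with a shared symbol stem and the 5 distances from Prdm1 were compared after their values had been seen, so the counts of the families are given without a test. Of cytochrome P450 genes (Cyp), 14 rose and 5 fell of 27. Of sorting nexins (Snx), which act in endosomal transport, 1 rose and 12 fell of 26, of vacuolar sorting genes (Vps) 0 rose and 9 fell of 29, and of genes of the proton pump and its relatives (Atp6) 1 rose and 8 fell of 17. The larger side was the same for these 4 under the deposited values, without background correction and with median scaling. Of ribosomal protein genes of the large subunit (Rpl), 7 rose and 0 fell of 33, but 2 rose under the deposited values and 0 with median scaling. Of those of the small subunit (Rps), 0 of 25 changed, with 1 higher under the deposited values and 3 without background correction. In the other families, 34 rose and 44 fell of 204 for Slc, 9 rose and 13 fell of 169 for Zfp, 6 rose and 4 fell of 20 for Gst, 3 rose and 8 fell of 15 for Mfsd, 5 rose and 1 fell of 15 for Aldh, 3 rose and 4 fell of 12 for Krt and 3 rose and 1 fell of 8 for Ugt. With median scaling the numbers were 24 and 43 for Slc, 1 and 11 for Zfp, 4 and 4 for Gst, 3 and 7 for Mfsd, 4 and 2 for Aldh, 3 and 4 for Krt and 1 and 1 for Ugt.

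Genes next to Prdm1 were not shown to change more often than others. Of the 20 tested genes nearest to it on its chromosome, 8 changed (4 higher, 4 lower), against 2307 of all 9961 (Fisher's exact test, p = 0.11, adjusted p = 0.28). Of the nearest 10, 40, 60 and 100, 3, 14, 17 and 25 changed, with adjusted p of 0.71, 0.28, 0.6 and 0.71. The histocompatibility gene H2-Bl took 2 levels over the samples, 6.46 to 8.45 log2 intensity in 9 and 10.89 to 12.64 in 12, of which 8 were labelled controls and 4 labelled mutants. Xist took 2 levels as well, with 6 of 11 labelled controls and 6 of 10 labelled mutants at 8.19 to 10.66 and the other 9 samples at 4.25 to 4.69. Bco1, a marker of the proximal small intestine, was detected in 5 labelled mutants and in no labelled control, and shared 1 library with the 6 in which Car1 and Hoxd10 were detected.

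The fall of genes used as liver markers was weighed against the dissection, with both tests on liver tissue and the choice of 3 libraries made after the result was seen. Controls 8, 9 and 11 stood apart in the liver score, at 0.80, 1.36 and 1.54 against 0.11 to 0.48 in the other 8 labelled controls. Of 11 tested liver markers, 7 read higher in each of these 3 than in any other labelled control, such as Ahsg (8.38 to 9.43 log2 intensity against 4.45 to 6.60) and Itih3 (7.10 to 7.71 against 6.13 to 6.48). Afp, which had the largest fall but is not on the liver list, read 7.72 to 7.78 in these 3 and 6.88 to 8.85 in the other 8. Liver tissue in these 3 libraries as the source of the whole fall is argued against: 4 of the 5 fallen markers, Ttr, Trf, Fga and Itih3, read higher on each of the other 8 control arrays than on every mutant array. A smaller contribution of liver tissue in these 3 stays open. Liver tissue in all control dissections alike stays open too. On most control arrays 45.5% of 22 liver markers were detected, and albumin, Apoh, Fgb, Serpinc1 and Fetub on 0 of 21 arrays, but as albumin was silent also where Ahsg was high, its absence excludes no liver RNA. In the other 8 labelled controls, the difference from labelled mutants was 2.57 log2 for Ttr and -0.38 for Ahsg, which liver tissue alone would not give if its transcripts came in fixed proportion. Whether the markers share 1 source of RNA stays open, because the mean r between the 5 that fell and the 6 other tested markers over the 11 control arrays was 0.32, between the bounds set for either answer. A change of these transcripts within the intestine itself, which the genotype offers, was not tested and stays open.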
